A study of Arabidopsis thaliana with 38 samples.

How the data were processed

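Poly(A)-selected RNA of Arabidopsis thaliana was sequenced from 4 genotypes, which the labels name H3.1, H3.1S28A, H3.3 and H3.3S28A, with 2 libraries of each. H3.1 and H3.3 are the main replication-coupled and replication-independent forms of histone H3, and S28A stands for an exchange of serine 28 for alanine. The labels give the source as seedlings 2 weeks old, while their extraction text names closed flower buds. For H3.1 and H3.3 the levels given at the start of Results argue against buds. The growth text covers both long and short days and does not say which was used for these libraries. The labels treat the 2 libraries of a genotype as separate samples and do not say whether they came from separate batches of plants, so the p-values below measure the spread between these samples only. The series also describes 30 chromatin immunoprecipitation libraries, which are not analysed here.

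The values are raw counts per gene, deposited by the authors in 2 tables, one with the H3.1 and H3.1S28A libraries and one with the H3.3 and H3.3S28A libraries. Columns were assigned to the samples by their names and order. The H3.1 columns were read as replicates 1 and 2 of H3.1, and only the H3.1S28A columns carry the word new, which the sources used here do not explain. Per the submitters' processing notes, HISAT2, Subread and DESeq2 were used with the genome build TAIR10. Their versions and settings, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies are therefore uncertain where they are named, as are genes that overlap on opposite strands. Each table held the same 27416 genes, and the 2 tables were joined by gene identifier. Both tables held only whole numbers, with column totals that differed between libraries. Gene names, gene neighbours and gene spans came from a RefSeq gene table of the assembly TAIR10.1, which held 26719 of the 27416 genes (97.5%). No coordinates are printed because that assembly is not the build of the files. Transcript lengths and GC content were not used here, and the share of transposable element genes was not computed because that table names no such class.

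Total counts ran from 12865999 to 24449528 per library. A count of 0 allows a level of up to 0.123 to 0.233 CPM (counts scaled to the library total), taken as 3 counts over the library total. Shares of counts carry 95% Wilson intervals, count ratios carry 95% exact intervals, and all intervals and floors cover counting error only.

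Each pair of genotypes was tested within its own table with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, glmQLFit and glmQLFTest), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The difference between the pairs was tested on all 8 libraries as the interaction contrast of the H3.1S28A effect minus the H3.3S28A effect, in which a difference in level between the tables cancels. A level set side by side across the tables is a comparison of libraries from separate tables. Log2 fold changes carry a standard error (SE), computed as the absolute log2 fold change over the square root of the test's F statistic. CPM of single genes are TMM-scaled and given as mean ± SD, while sums over a list are scaled to the library total alone. Where a group had no count, the fold is a lower limit computed from 3 counts over the whole group. Where a group had 1 to 3 counts, the ratio of depth-scaled counts is given with its counting interval.

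Before the data were examined, 19 gene lists with 330 members were written from general knowledge: histone H3.1 genes, other H3 genes, flowering time regulators, floral organ identity genes, meristem regulators, seed and embryo genes, Polycomb and H3K27 machinery, DNA methylation and silencing factors with histone chaperones, cell cycle genes, DNA damage genes, anther and tapetum, pollen, leaf and root markers, and salicylic acid, jasmonate, heat, cold and clock genes. All 330 members were in the files, and the RefSeq table held the symbol used here for 307. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, and camera with an estimated correlation and the rotation test fry were run beside it. That correlation was estimated from 2 libraries per group, and neither it nor fry was tried on the simulated counts described below. A list not called with an estimated correlation is therefore not shown to be unchanged.

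The rule for named genes was fixed at the same time. For each pair it took all histone H3 genes of the lists, then FLC, FT, SOC1, AGL24, SEP3, AG, AP3, PI and MEA, whatever their result. It added the 8 genes with a symbol and the 4 without one that had the largest fold change in each direction, among those with adjusted p under 0.05, at least 1 CPM in the higher group and replicates that did not overlap. From each list it took up to 4 members with the smallest adjusted p, and for the difference between pairs the 6 largest in each direction. Other genes named below were chosen after their values were seen, and the text says so where they appear.

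Alternatives chosen before the data were examined were size factors by the median of ratios, no filter on low counts, a mean of at least 1 CPM in a group, the replicate number as a block, organelle genes left out (88 of the chloroplast and 122 of the mitochondrion), DESeq2 1.42.0 as the test, a fold change of at least 1 on the log2 scale, all 8 libraries in 1 fit, the other set tests and each library left out in turn. Where 1 library of a group was left, it was assumed to vary like the other group. Removal of a trend of fold change with gene span, through a smooth curve per library (lowess span 0.3), was added after seeing the data, alone and together with an estimated correlation. So were 14 gene families taken by symbol from the RefSeq table, a set of genes with a known time of day, the floral and list-matched tests, and the spread that decides whether the correlation of fold changes moved (SD 0.0701 over the 8 fits without 1 library).

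The procedure was tested on simulated counts with the real means and library sizes, in which 100 genes changed by 1 and 100 by 2 on the log2 scale. In the H3.1 pair (18974 genes) 75% and 99% were recovered and 0.129% of unchanged genes were called. In the H3.3 pair (19729 genes) these values were 77%, 95% and 0.198%, and for the difference (20052 genes) 52%, 80% and 0.128%. When a gene span trend was simulated as well, 12.7%, 11.8% and 4.29% of unchanged genes were called, and 0.0966%, 0.155% and 0.103% after the trend was removed. Camera called 23.5%, 22.2% and 35.3% of 17 or 18 unshifted lists with that trend. These shares were 0%, 5.88% and 5.56% without it and 0%, 5.56% and 5.88% after its removal. A list call before the removal can therefore come from such a trend alone. The simulated trend had the same downward slope in every comparison and was not fitted to the data. The real trends differed (Spearman rho −0.218 in the H3.1 pair, −0.524 in the H3.3 pair and 0.418 for the difference), so these rates are not those of the data.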

Results

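RNA was sequenced from Arabidopsis thaliana plants of 4 genotypes to ask how an exchange of serine 28 of histone H3 for alanine, made either in the replication-coupled form H3.1 or in the replication-independent form H3.3, alters gene expression. Serine 28 lies next to lysine 27, the residue that Polycomb repressive complexes methylate. There were 2 libraries per genotype, 8 in all, and each mutant genotype was compared with the genotype that carried the unmutated form of the same histone. Total gene counts were 20624191 and 22285836 in H3.1, 14679021 and 24449528 in H3.1S28A, 19630779 and 18914850 in H3.3, and 19738850 and 12865999 in H3.3S28A. Between 21427 and 22667 of the 27416 genes had a count in a library, and the 10 most abundant genes took 10.7% to 13.3% of the counts. Replicates correlated at r = 0.993 in H3.1, 0.990 in H3.1S28A, 0.992 in H3.3 and 0.984 in H3.3S28A, across the log2 CPM of genes, which are not independent replicates. The counts of each pair of replicates differed by more than sampling noise (chi-square per degree of freedom from 4.20 to 19.5), so no library was a copy of another. H3.3S28A replicate 2 stood apart from the other libraries: chloroplast genes took 0.858% of its counts (95% Wilson interval 0.853% to 0.863%) against 0.0520% to 0.143% elsewhere, and the single locus AT2G01021, chosen after its value was seen, took 0.753% (0.748% to 0.757%) against 0.0204% to 0.0635%. Leaf photosynthesis genes took 144220 to 166157 CPM in every library, and the 35 anther, tapetum and pollen markers together took 14.5 to 37.0 CPM. With all 8 libraries scaled together, the floral organ identity genes AP3 and PI were at most 0.0447 and 0.320 CPM in H3.1 and H3.3. These levels argue against closed flower buds as the source of the H3.1 and H3.3 libraries. Whether the H3.1S28A and H3.3S28A samples held some flower tissue beside leaves stays open. Levels below are TMM-scaled CPM, given as mean ± SD with n = 2 libraries, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Sums over listed genes, above and below, are CPM of the library total without TMM scaling.

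In H3.1S28A plants, 4 of 7 floral organ identity genes were called higher and 3 of 10 meristem regulators lower than in H3.1 plants. Both lists were called by camera and were at adjusted p = 0.680 with an estimated correlation. SEPALLATA3 (SEP3, AT1G24260), a MADS-box factor of floral organ identity, rose from 0.901 ± 0.016 to 24.2 ± 26.9 CPM (log2 fold change 4.69, SE 0.79, adjusted p = 0.0020). KNAT1 (AT4G08150), a homeobox gene of the shoot meristem, fell from 4.19 ± 0.12 to 0.805 ± 0.359 CPM (log2 fold change −2.45, SE 0.35, adjusted p = 6.9e-04). The pathogenesis-related genes PR2 and PR5 fell and the chlorophyll-binding protein gene LHCB5 rose. ABCG19 (AT3G55130), which encodes an ABC transporter, dropped from 809 and 960 counts to 2 and 0. In all, 1562 genes were higher and 998 lower in H3.1S28A among 18974 tested (13.5%), of which 229 and 219 changed at least 2-fold. At an unadjusted p under 0.05 there were 5511 genes. Without H3.1 replicate 1 the calls numbered 1324, and without H3.1 replicate 2 they numbered 1152. Fold changes declined with gene span in this pair (Spearman rho −0.218 across genes), and 1136 of the higher and 803 of the lower genes kept their call once that trend was removed. Single H3.1S28A libraries set against single H3.1 libraries gave rho from −0.279 to −0.0991. Replicate 1 against replicate 2 gave −0.138 in H3.1 and −0.189 in H3.1S28A, so the trend overlapped in size with that between replicates.

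**Figure D1:**
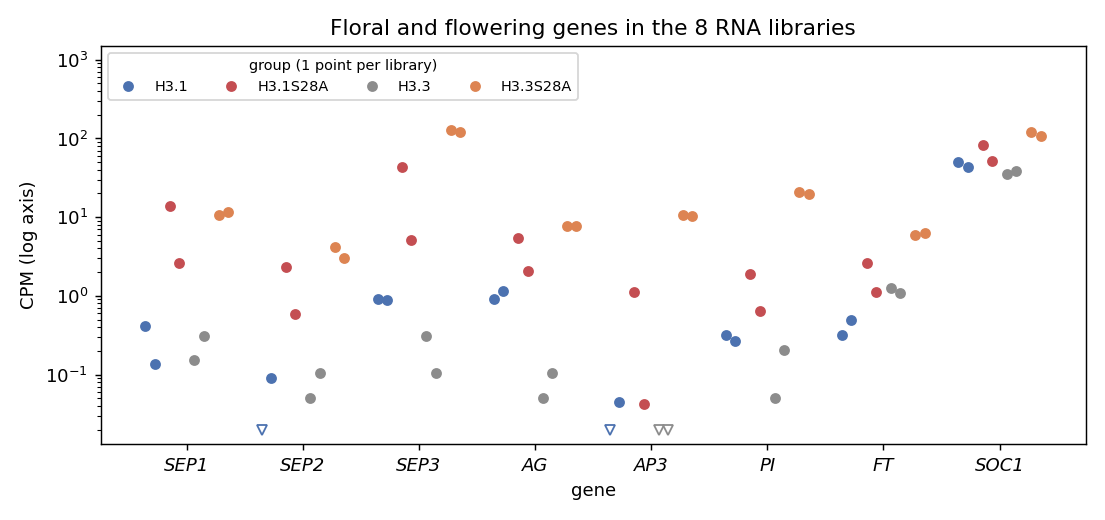
CPM on a log axis of 8 floral and flowering genes, with 1 point per library, 2 libraries per group, and open triangles for libraries without a count. SEP3 lay at 129.6 and 122 CPM in H3.3S28A, at 43.2 and 5.15 CPM in H3.1S28A and below 1 CPM in H3.1 and H3.3, with all 8 libraries scaled together.

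Of the 7 floral organ identity genes tested in the H3.1 pair, 4 rose, none fell and 3 were not called, or 5 rose when adjusted over the list alone. SEP1 (AT5G15800) rose from 0.272 ± 0.196 to 8.14 ± 7.85 CPM (log2 fold change 4.82, adjusted p = 0.0013). SEP2 (AT3G02310) had 0 and 2 counts in H3.1 and 33 and 14 in H3.1S28A (ratio 27.7, 95% interval 7.24 to 235, adjusted p = 0.0078). AGAMOUS (AG, AT4G18960), which specifies stamens and carpels, rose from 1.03 ± 0.17 to 3.74 ± 2.40 CPM (adjusted p = 0.017). The 2 mutant libraries differed widely, with 612 and 121 counts of SEP3 and 90.6 and 34.2 CPM for the sum of the 16 listed floral genes, against 29.6 and 28.9 CPM in H3.1. PISTILLATA (PI) had a log2 fold change of 2.01 (adjusted p = 0.0524), and AP3 had 0, 1, 16 and 1 counts, too few to be tested. The list shifted up by camera (median log2 fold change 2.01, adjusted p = 4.4e-04), with adjusted p = 0.680 with an estimated correlation. SEP1, SEP2 and PI had few counts in H3.1 and passed the count filter through H3.1S28A, so they could not be called lower. AG kept its log2 fold change of 1.79 but lost its call without H3.1 replicate 1 or 2 (1.64 and 1.98, adjusted p = 0.0843 and 0.0655), and was at 0.97 (0.156) without H3.1S28A replicate 1, where PI was at 1.11 and SEP3 was still called, at 5.67-fold. SEP2 lost its call without H3.1 replicate 1 (0.0566). PI was called without H3.1S28A replicate 2 (0.0012), without the count filter (0.0362), with the replicate number as a block (0.0386), without organelle genes (0.0497) and with all 8 libraries in 1 fit (0.0314).

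Among 26 flowering time regulators, 3 rose and 6 fell, or 6 and 8 when adjusted over the list alone, and the list did not shift (camera adjusted p = 0.413). FT (AT1G65480), which encodes the mobile flowering signal, rose from 0.404 ± 0.120 to 1.86 ± 1.07 CPM (adjusted p = 0.0203), as did the squamosa-promoter genes SPL3 (log2 fold change 1.08) and SPL4 (0.81). The floral repressors TOE1 (131 ± 16.8 to 79.6 ± 17.2 CPM, log2 fold change −0.71) and SNZ (−0.63) fell. FLC, a repressor of flowering silenced by Polycomb proteins, was not called, with a log2 fold change −0.20 (adjusted p = 0.589), and neither was its target SOC1, with 46.4 ± 5.5 and 67.2 ± 22.5 CPM (0.53, 0.0660). The FT call was lost without H3.1 replicate 1 (adjusted p = 0.139), H3.1 replicate 2 (0.0861) or H3.1S28A replicate 1 (0.149), SPL3 without H3.1 replicate 2 (0.0598) and SPL4 without H3.1 replicate 1 (0.0652). SOC1 was at 0.84 and called without H3.1S28A replicate 2 (2.8e-08), at 0.14 without H3.1S28A replicate 1, and called without the count filter (0.0128) and with the replicate number as a block (0.0136).

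None of 10 meristem and homeobox regulators rose and 3 fell, the same numbers as when adjusted over the list alone. The genes that fell were KNAT1, WOX1 (3.43 ± 0.57 to 1.31 ± 0.05 CPM, log2 fold change −1.39) and STM (3.53 ± 0.92 to 1.32 ± 1.03 CPM, −1.54, adjusted p = 0.0353). With the span trend removed STM was at −1.49 (adjusted p = 0.0645). The list shifted down (median −1.05, camera adjusted p = 5.0e-04, and adjusted p = 0.680 with an estimated correlation). Without H3.1S28A replicate 2 the camera value was 0.0533 and STM was at −0.78 (0.126), against −2.56 without H3.1S28A replicate 1, and DESeq2 gave 0.0540 for STM. STM was at 0.253 without H3.1 replicate 2, and WOX1 at 0.108 without H3.1 replicate 1. Of 4 seed and embryo genes, 1 fell, AGL15, a MADS-box gene of embryos (2.05 ± 0.13 to 0.424 ± 0.000416 CPM, log2 fold change −2.26, adjusted p = 0.0046; camera adjusted p = 0.271). The seed list was called down without H3.1S28A replicate 1 (0.0384).

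Of 5 H3.1 genes, HTR1 rose slightly (111 ± 0.989 to 141 ± 1.90 CPM, log2 fold change 0.34, adjusted p = 0.0369) and 4 were not called, with HTR2, HTR3 and HTR9 at 0.04, 0.24 and 0.19. HTR1 was not called without any of the 4 libraries (adjusted p = 0.0709 to 0.151), and with the span trend removed HTR1 and HTR4 were at 0.05 and 0.32 (adjusted p = 0.778 and 0.0513). HTR13 had 149.95 ± 3.12 CPM in H3.1 and 157 and 63.9 CPM in the 2 H3.1S28A libraries (log2 fold change −0.45, adjusted p = 0.293), and −1.23 (6.4e-14) without H3.1S28A replicate 1. Of 6 other H3 genes, HTR4 rose (182 ± 1.13 to 246 ± 7.23 CPM, 0.44, adjusted p = 0.0113), and HTR5, HTR8, HTR6, HTR12 and HTR11 were not called (0.08, 0.22, −0.78, −0.28 and 0.47). HTR10, HTR14 and HTR15 fell under the count filter, as did MEA. The 2 histone lists gave the same counts when adjusted over the list alone and did not shift (camera adjusted p = 0.427 and 0.453). H3 genes are near-identical copies, and how reads were shared between them is not stated. Reads of any introduced H3 copy would be counted with them as well.

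Chromatin and cell cycle genes showed few calls in this pair. Among 29 Polycomb and H3K27 genes only ULT1, which encodes a trithorax group protein, was called (8.53 ± 0.06 to 15.4 ± 3.1 CPM, log2 fold change 0.87, adjusted p = 0.0048; list camera adjusted p = 0.453). None of 13 genes for DNA methylation, silencing and histone chaperones was called by edgeR's quasi-likelihood test, 4 had an unadjusted p under 0.05 and DESeq2 called 0 (camera adjusted p = 0.0819, and 0.0381 in the downward direction without H3.1S28A replicate 2). Of 26 cell cycle genes CYCD3;3 rose (0.49) and the cytokinesis kinesin HINKEL (−0.59) and the anaphase activator CDC20.1 (−0.51) fell (camera adjusted p = 0.185, and 0.0162 in the downward direction without H3.1S28A replicate 2). Each of these calls was lost when single libraries were left out: HINKEL without H3.1 replicate 1, H3.1 replicate 2 or H3.1S28A replicate 1 (adjusted p = 0.106, 0.0672 and 0.101) and CDC20.1 without H3.1 replicate 1 or H3.1S28A replicate 1 (0.254 and 0.135). CYCD3;3 was not called without H3.1 replicate 1, H3.1 replicate 2 or H3.1S28A replicate 2 (0.202, 0.156 and 0.0748) or by DESeq2 (0.141). Without H3.1S28A replicate 1 HINKEL and CDC20.1 were at −0.33 and −0.31. With the span trend removed HINKEL, CDC20.1 and CYCD3;3 were at −0.50, −0.48 and 0.40 (adjusted p = 0.0506, 0.0593 and 0.0964). All these counts were the same when adjusted over the list alone. None of 4 DNA damage genes (1 at an unadjusted p under 0.05), 2 anther and tapetum markers (0) or 4 pollen markers (0) was called by edgeR, and DESeq2 called 0 in each. The DNA damage and pollen lists had camera adjusted p = 0.665 and 0.283. PHO1 fell (16.7 ± 4.1 to 9.42 ± 0.54 CPM, −0.82, adjusted p = 0.0087) among 4 root markers, 2 when adjusted over the list alone, and was at −0.55 (0.131) without H3.1 replicate 2. The root list was called down at camera adjusted p = 0.0462, with adjusted p = 0.680 with an estimated correlation, 0.376 without H3.1 replicate 2, 0.360 without H3.1S28A replicate 1, 0.403 without the count filter, 0.356 with all 8 libraries in 1 fit and 0.0711 with the span trend removed.

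Leaf photosynthesis genes rose as a list, with 8 of 22 higher and none lower, or 12 when adjusted over the list alone (median log2 fold change 0.26, camera adjusted p = 4.4e-04, and adjusted p = 0.680 with an estimated correlation). LHCB5 rose from 4720.3 ± 44.4 to 7551 ± 167 CPM (0.68, adjusted p = 4.8e-04), and LHCB2.1, LHCB6 and LHCA3 had log2 fold changes of 0.45, 0.40 and 0.39. With the span trend removed 1 member was higher, LHCB2.1, LHCB6 and LHCA3 were at adjusted p = 0.0972, 0.152 and 0.127, and the leaf list was at 0.0558. Without H3.1S28A replicate 1, LHCB2.1, LHCB6 and LHCA3 were at adjusted p = 0.161, 0.176 and 0.198, and without H3.1S28A replicate 2 LHCB6 and LHCA3 were at 0.0513 and 0.0713. Salicylic acid and defence genes fell as a list (3 of 15 lower and none higher, 5 lower when adjusted over the list alone, camera adjusted p = 0.0029, and adjusted p = 0.680 with an estimated correlation). The called members were PR2 (AT3G57260) from 8.44 ± 0.71 to 2.06 ± 0.09 CPM (−2.04, adjusted p = 1.2e-04), PR5 from 26.8 ± 2.8 to 9.43 ± 2.86 CPM (−1.48, 2.4e-04) and ACD6 from 49.2 ± 2.3 to 23.2 ± 5.5 CPM (−1.10, 3.9e-04). The defence list was at 0.106 without H3.1S28A replicate 2.

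Of 15 jasmonate genes, the biosynthesis genes LOX2 (−1.13, and −1.06 with the span trend removed) and AOC2 (−0.82) fell and none rose, as when adjusted over the list alone. Both rested on H3.1 replicate 2, without which they were at −0.18 and −0.37 (adjusted p = 0.398 and 0.127), LOX2 was at 0.0722 with the span trend removed, and DESeq2 called 0 of the list (LOX2 0.364 and AOC2 0.192). The jasmonate list was called down at camera adjusted p = 0.0462 (adjusted p = 0.680 with an estimated correlation, 0.0667 with the span trend removed, 0.496 without H3.1S28A replicate 2), and without H3.1 replicate 2 its direction turned, at 0.376. HSP90.1 rose (0.92, adjusted p = 0.0398) among 6 heat shock genes (camera adjusted p = 0.397), and was not called without H3.1 replicate 1, H3.1 replicate 2 or H3.1S28A replicate 1 (0.164, 0.135 and 0.165) or by DESeq2 (0.112). Of 10 cold and dehydration genes RAB18 rose (0.77) and RD29A (−0.90), COR15A (−0.67) and COR15B (−0.56) fell, with camera adjusted p = 0.397 for the list. COR15A and COR15B were at adjusted p = 0.101 and 0.257 without H3.1 replicate 1, where COR15B was at −0.33 and RD29A, at 0.0860 by DESeq2, was at −0.50. RAB18 was at 0.0512 with the span trend removed and at 0.157 without H3.1 replicate 2, when the cold list itself was called down (0.0037). Both lists gave the same counts when adjusted over the list alone. Of 15 clock genes, the evening genes PRR5 (72.9 ± 6.1 to 36.6 ± 5.9 CPM, −0.99, adjusted p = 3.8e-04), TOC1 (47.5 ± 5.8 to 26.0 ± 2.1 CPM, −0.87, 6.1e-04) and FKF1 (−1.07, 0.0061) fell and none rose, or 5 fell and 1 rose when adjusted over the list alone. The clock list was called down at camera adjusted p = 0.0405 (adjusted p = 0.680 with an estimated correlation, 0.0667 with the span trend removed, 0.229 without H3.1 replicate 1, where FKF1 was at −0.65 and 0.0768). With fry no list passed in the H3.1 pair, and neither fry nor camera with an estimated correlation had a list at an unadjusted p under 0.05. The median log2 fold change of the jasmonate, root and clock lists moved little with the span trend removed. It went from −0.561 to −0.519, from −0.340 to −0.335 and from −0.097 to −0.130.

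Among the genes with large increases in H3.1S28A were the lipid transfer protein genes LTP4 (0.543 ± 0.264 to 21.1 ± 19.9 CPM, log2 fold change 5.23, adjusted p = 4.2e-04) and LTP3 (3.20 ± 0.26 to 21.1 ± 20.3 CPM, 2.67, 0.0059). Others were CER4, a fatty acyl reductase of wax synthesis (0.880 ± 0.239 to 5.33 ± 2.74 CPM, 2.56, 0.0012), PHI-1 (2.78, 0.0081) and SAG29 (3.37, 0.0227). Among loci without a symbol these were AT1G03710 (3.71, 6.1e-04), AT2G45135 (3.59), AT1G02770 (3.05) and AT5G60610 (2.87). Among the decreases was ABCG19, whose ratio of counts was 0.00133 (95% interval 1.6e-04 to 0.00481, adjusted p = 7.2e-09). The extensin gene EXT3, of the cell wall, fell from 43.1 ± 12.9 to 6.60 ± 0.64 CPM (−2.72, 2.8e-06). UMAMIT32 (−3.47), UMAMIT14 (−2.93), TAT3 (−3.37), CWINV5 (−2.58, and −2.59 with the span trend removed), WRKY14 (−2.53), AT4G22485 (−2.72), AT4G15160 (−3.20) and AT3G59270 (−2.57) fell as well. AT1G27565 had 34 and 11 counts against 2 and 0 (ratio 0.0523, 95% interval 0.00615 to 0.200). TAT3 and CWINV5 rested on H3.1 replicate 2, without which they were at −0.74 and −1.34 (adjusted p = 0.573 and 0.560). Without that library, when calls in the pair numbered 1152 against 2560, other genes kept most of their fold but missed the threshold: PHI-1 (2.24, 0.0990), UMAMIT32 (−3.02, 0.0576), UMAMIT14 (−2.61, 0.0638), WRKY14 (−2.41, 0.0869), AT4G15160 (−2.59, 0.190), AT3G59270 (−2.47, 0.0873) and AT5G60610 (2.16, 0.211). SAG29 kept its fold but not its call without H3.1 replicate 1 or 2 (3.14 and 3.68, 0.0928 and 0.0960), and was at 1.16 (0.479) without H3.1S28A replicate 1. LTP3 and AT2G45135 were at 1.07 and 2.24 without that library. AT5G60610 was not called without H3.1 replicate 1 or H3.1S28A replicate 1 (0.0502 and 0.105), nor CWINV5 without H3.1S28A replicate 2 (−1.71, 0.108), with all 8 libraries in 1 fit (0.0616) or with the span trend removed (0.0653). Without H3.1S28A replicate 2 AT3G59270 was at −1.68 and AT4G22485 at −4.83. DESeq2 gave adjusted p = 0.149 for AT4G22485, 0.0863 for LTP3, 0.105 for SAG29 and 0.127 for TAT3.

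In H3.3S28A plants, all 10 floral organ identity genes tested rose, most from near 0, with SEP3 going from 0.201 ± 0.139 to 129 ± 5.79 CPM (log2 fold change 9.26, SE 0.19, adjusted p = 9.7e-10). The flowering promoters FT and SOC1 rose, as did 7 of 12 cold genes and 13 of 19 defence genes, and 7 of 15 clock genes rose and 7 fell. Lower were 17 of 26 cell cycle genes, 11 of 13 DNA methylation and silencing genes and 14 of 29 Polycomb and H3K27 genes, and the last 2 lists were not called with the gene span trend removed (camera adjusted p = 0.127 and 0.150). Camera called 6 of 19 lists, and with an estimated correlation 0, with 1 at an unadjusted p under 0.05. Among 19729 genes tested, 5674 were higher and 5855 lower (58.4%), of which 1976 and 2523 changed at least 2-fold. A decline of fold change with gene span ran through this pair (Spearman rho −0.524 across genes). In the shortest decile of genes (median span 935 bp) 53.6% were higher with a median log2 fold change of 0.65, and in the longest decile (5746 bp) 78.7% were lower with a median of −1.02. Once the trend was removed, 5290 genes were higher and 4577 lower, 3866 and 3684 of the calls kept their direction, and 403 were called in the other direction.

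**Figure D2:**
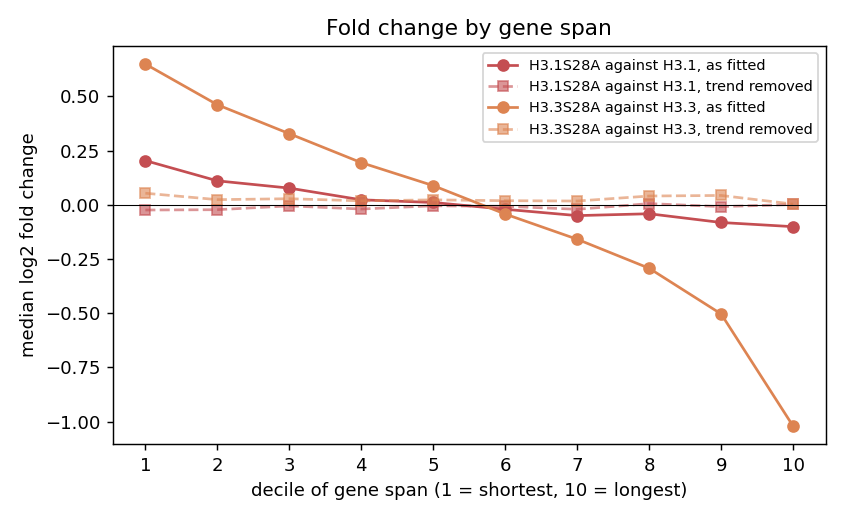
Median log2 fold change of the genes in each decile of gene span (1 shortest, 10 longest) for both pairs, as fitted (solid) and with the span trend removed (dashed). The H3.3 pair runs from 0.65 to −1.02 and the H3.1 pair from 0.20 to −0.10 as fitted.

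Among the floral genes that rose, AP3 (AT3G54340), of petals and stamens, had no count in H3.3 and 10.7 ± 0.16 CPM in H3.3S28A (at least 141-fold higher). Its partner PI (AT5G20240) went from 0.128 ± 0.110 to 20.9 ± 1.07 CPM (log2 fold change 7.29, adjusted p = 5.8e-08). SEP1 went from 0.229 ± 0.112 to 11.4 ± 0.645 CPM (5.61, 3.1e-07), and AG from 3 counts to 7.81 ± 0.05 CPM (ratio 103, 95% interval 34.9 to 503). All 10 were also higher when adjusted over the list alone. Those with few or no counts in H3.3 passed the count filter through H3.3S28A and so could not be called lower. Listed genes low in both groups were not tested, so these numbers are in part set by the filter. SEP4 and AP2, named because they were expressed in both groups, rose as well. They went from 9.89 and 8.71 to 17.9 and 15.7 CPM and from 18.8 and 17.3 to 25.4 and 29.3 CPM, with all 8 libraries scaled together. The list had a median log2 fold change of 5.54, also with AP3 at its bound (camera adjusted p = 4.5e-18, fry adjusted p = 0.0030, and adjusted p = 0.354 with an estimated correlation, the unadjusted value being 0.0186). The summed level of the 16 listed floral genes was 28.9 ± 1.5 CPM in H3.3 and 235.9 ± 4.5 CPM in H3.3S28A. Removal of the span trend left the floral list called (3.9e-26, and adjusted p = 0.146 with an estimated correlation, the unadjusted value being 0.0077).

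Among 29 flowering time regulators 14 rose and 4 fell, the same numbers as when adjusted over the list alone. FT rose from 1.16 ± 0.12 to 6.27 ± 0.22 CPM (log2 fold change 2.42, adjusted p = 3.5e-05), SOC1 (AT2G45660) from 36.3 ± 2.7 to 118 ± 10.8 CPM (1.70, 1.9e-07). AGL24 rose from 6.01 ± 1.17 to 21.7 ± 0.46 CPM (1.85, 3.4e-06) and FUL from 1.97 ± 0.11 to 13.9 ± 3.9 CPM (2.82, 3.6e-06). TEM2 (AT1G68840), a repressor of FT, fell from 82.3 ± 10.2 to 9.99 ± 1.02 CPM (−3.05, 4.2e-08). The repressor FLC rose as well (1.44 ± 0.37 to 3.67 ± 0.31 CPM, 1.34, 0.0057), and was at 0.0575 without H3.3 replicate 2 and at 2.36 with the span trend removed. The flowering time list missed the threshold (camera adjusted p = 0.0547, 0.705 with an estimated correlation and 0.0966 by fry), passed it with the span trend removed (4.1e-04, and adjusted p = 0.575 with an estimated correlation), with a filter at 1 CPM (0.0496) and without H3.3 replicate 1, H3.3 replicate 2 or H3.3S28A replicate 2 (0.0156, 0.0333 and 0.0196). Of 11 meristem regulators STM (1.40, 3.4e-04), CUC2 (2.19) and KNAT6 (0.85) rose and WOX1 (−0.90) and KNAT1 (−0.63) fell, or 2 rose and none fell when adjusted over the list alone (camera adjusted p = 0.563). KNAT1 is outside the rule for named genes in this pair and was added because the count was small. CUC2 was not called without H3.3 replicate 2 or H3.3S28A replicate 1 (adjusted p = 0.0831 and 0.0518). KNAT6 and WOX1 were not called without H3.3 replicate 1 (0.180 and 0.0710), H3.3 replicate 2 (0.0863 and 0.177) or H3.3S28A replicate 2 (0.275 and 0.166), nor by DESeq2 (0.0626 and 0.112), and KNAT6 was at 0.0674 with all 8 libraries in 1 fit. With the span trend removed KNAT6 was at 1.74, and WOX1 at −0.78 was not called (0.0779). Of 4 seed genes PHE1 rose (1.18 ± 0.44 to 3.46 ± 0.29 CPM, 1.54, 0.0043; camera adjusted p = 0.750), and was at 0.98 with the span trend removed.

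The H3.3 gene HTR5 (AT4G40040) rose from 703 ± 25.7 to 1228 ± 42.4 CPM (log2 fold change 0.80, adjusted p = 3.1e-06). HTR8, another H3.3 gene, rose from 107 ± 4.9 to 147 ± 0.15 CPM (0.46, 1.5e-04), while HTR4, the remaining H3.3 gene, was at 0.07 (0.461). HTR15 had no count in H3.3 and 36 and 13 in H3.3S28A (at least 20.4-fold higher), and HTR6 rose (2.61, 0.0189) but not without H3.3 replicate 1 (1.58, 0.0752) or by DESeq2 (0.295). HTR12, the centromeric H3, and HTR11 were at 0.00 and −0.39, so that 4 of 7 other H3 genes were higher, also when adjusted over the list alone (camera adjusted p = 0.151). Among 5 H3.1 genes HTR9 fell (−0.24, 0.0277), none when adjusted over the list alone, and HTR1, HTR2, HTR3 and HTR13 were at 0.00, 0.13, −0.07 and 0.08 (camera adjusted p = 0.986). HTR9 was not called without H3.3 replicate 1, H3.3 replicate 2 or H3.3S28A replicate 2 (0.112, 0.0801 and 0.0706) or by DESeq2 (0.0729). H3.1 genes are short (median span 764 bp), and with the span trend removed all 5 were lower (camera adjusted p = 0.0015, and adjusted p = 0.575 with an estimated correlation). HTR4 (−0.29, 0.0050) and HTR11 (−1.08, 0.0439) were then lower as well, HTR8 was at −0.07 and HTR6 was not called (0.0727). HTR13 had 31.4 ± 0.5 CPM in H3.3 and 149.95 ± 3.12 CPM in H3.1, and HTR5 703 against 335, in separate tables. Reads of any introduced H3 copy would be counted with such genes, so a change in these levels need not come from the gene itself. The series describes no RNA library of Col, the other genotype of its chromatin libraries. HTR10, HTR14 and MEA fell under the count filter.

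Polycomb and H3K27 genes were lower in 14 of 29 cases and higher in 2 (the same when adjusted over the list alone, median log2 fold change −0.62, camera adjusted p = 0.0032, and adjusted p = 0.612 with an estimated correlation). SDG8 (AT1G77300), an H3K36 methyltransferase, fell from 30.2 ± 3.5 to 5.10 ± 0.93 CPM (−2.55, adjusted p = 4.0e-07), the H3K27 demethylases REF6 and ELF6 fell (−2.40 and −2.20), and the H3K27 methyltransferase SWN fell from 25.8 ± 0.6 to 8.58 ± 1.03 CPM (−1.57, 2.9e-06). DNA methylation and silencing genes were lower in 11 of 13 cases and higher in none, also when adjusted over the list alone (median −1.31, camera adjusted p = 4.6e-05, and adjusted p = 0.612 with an estimated correlation). They included the methyltransferase genes CMT2 (AT4G19020, 45.8 ± 2.4 to 7.07 ± 1.69 CPM, −2.67) and MET1 (−1.42), the chromatin remodeller ATRX (−2.23) and the demethylase IBM1 (−1.59). Both lists hold long genes (median span 3592 and 5570.0 bp), and with the span trend removed 9 and 8 members were lower, 3 and 2 higher, and the lists were at camera adjusted p = 0.150 and 0.127. The named genes were then closer to 0: SDG8 −1.07, REF6 −1.49, ELF6 −1.23, SWN −0.69, CMT2 −1.53, MET1 −0.36, ATRX −0.71 and IBM1 −0.38, the last at adjusted p = 0.0453.

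Cell cycle genes were lower in 17 of 26 cases and higher in 4, also when adjusted over the list alone (median −0.82, camera adjusted p = 5.5e-04, and adjusted p = 0.612 with an estimated correlation). HINKEL fell from 30.4 ± 5.1 to 6.26 ± 0.99 CPM (−2.26, adjusted p = 1.0e-06), CDC20.1 and CDC20.2 fell (−1.52 and −1.53), and the replicative helicase gene MCM4 fell (−1.52, 3.3e-06). The cell cycle list, with a median span of 2424 bp, stayed called with the span trend removed (18 lower, 1 higher, camera adjusted p = 6.0e-05, and adjusted p = 0.575 with an estimated correlation), with HINKEL at −1.49 and MCM4 at −0.88. Of 4 DNA damage genes PARP2 (−1.13) and BRCA1 (−1.11) fell and SMR7 rose (2.77, 0.0047), also when adjusted over the list alone. The median of that list was −0.60, its mean 0.11 and its camera adjusted p 0.823 with a downward direction. PARP2 and BRCA1 were at 0.0927 and 0.209 with the span trend removed, and SMR7 at 0.0570 without H3.3S28A replicate 2.

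Markers of reproductive cells moved down where they were called. Among 5 anther and tapetum markers LAP6 (−1.91) and TKPR1 (−0.82) fell (the same when adjusted over the list alone, camera adjusted p = 0.563). Among 4 pollen markers ANX1 fell (−1.13) and VGD1 had 15 and 10 counts against 0 and 1 (ratio 0.0499, 95% interval 0.00121 to 0.305), with 3 lower when adjusted over the list alone (camera adjusted p = 0.449). VGD1 was at 0.110 without H3.3S28A replicate 1, and ANX1 at 0.0955 with the span trend removed. Of 6 root markers PYK10 (−0.96), SCR (−0.97), SHR (−0.78) and PHO1 (−0.98) fell and NRT2.1, named because it was the only one, rose (2.21, 0.0112), or 4 fell and 2 rose when adjusted over the list alone. The root list had a median of −0.87, a mean of 0.04 and a camera adjusted p of 0.314 with a downward direction, and PHO1 turned to 0.03 with the span trend removed. Leaf photosynthesis genes were split, 5 of 22 higher and 8 lower, also when adjusted over the list alone (median −0.03, camera adjusted p = 0.824). RCA, the Rubisco activase gene, fell from 5911 ± 4.95 to 3326 ± 227 CPM (−0.83, 2.5e-06), LHCA1 (−0.53) and LHCB2.2 (−0.45) fell, and RBCS3B rose from 10556 ± 398 to 14884 ± 1349.8 CPM (0.50, 1.5e-04). With the span trend removed, 16 leaf genes were lower and none higher by edgeR (camera adjusted p = 0.0017, and adjusted p = 0.588 with an estimated correlation), LHCA1 and LHCB2.2 were at −0.83 and −0.95, and RBCS3B was at 0.0734.

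Defence genes were higher in 13 of 19 cases and lower in 4, also when adjusted over the list alone (median 0.86, camera adjusted p = 0.0305, adjusted p = 0.676 with an estimated correlation and 0.0966 by fry). PR2 rose from 7.41 ± 2.58 to 76.6 ± 26.2 CPM (log2 fold change 3.37, adjusted p = 1.2e-06) and PR5 from 7.69 ± 2.47 to 113 ± 50.9 CPM (3.88, 1.3e-06). PR1 (AT2G14610) rose from 9.44 and 0.872 CPM to 359 and 109 CPM (5.50, 4.5e-05), a wide spread between replicates. The signalling gene EDS1 fell from 20.7 ± 1.65 to 7.42 ± 2.53 CPM (−1.45, 8.8e-05). Of 15 jasmonate genes 6 rose and 4 fell, or 6 and 5 when adjusted over the list alone (camera adjusted p = 0.190, and 0.0333 without H3.3 replicate 2). The defensin gene PDF1.2A (AT5G44420), a near-identical copy of other PDF1.2 genes, rose from 0.125 ± 0.105 to 27.9 ± 0.42 CPM (7.71, 2.0e-08), VSP1 (1.40) and AOC2 (0.77, and 0.35 with the span trend removed) rose and CORI3 fell (−0.77). VSP1 and CORI3 were at 0.162 and 0.0873 when all 8 libraries shared 1 fit.

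Of 12 cold and dehydration genes 7 rose and 1 fell, also when adjusted over the list alone (median 0.81, camera adjusted p = 1.4e-06, and adjusted p = 0.612 with an estimated correlation). KIN1 (AT5G15960) rose from 3.67 ± 0.18 to 42.6 ± 1.85 CPM (3.54, adjusted p = 2.3e-08) and KIN2 from 152 ± 18.4 to 868 ± 130.5 CPM (2.51). COR15A rose from 132 ± 1.5 to 411 ± 31.2 CPM (1.64) and COR15B from 107 ± 9.0 to 374 ± 16.6 CPM (1.80). Among 12 heat shock genes 6 rose and none fell, or 4 when adjusted over the list alone (median 1.09, camera adjusted p = 0.176, fry adjusted p = 0.0030). HSP18.2 went from 9.69 ± 0.08 to 20.5 ± 0.8 CPM (1.08, 3.6e-05, and 0.48 with the span trend removed), HSP17.4 from 3 counts to 41 (ratio 17.0, 95% interval 5.43 to 86.0) and HSP23.6 from no count to 11 and 9 (at least 8.31-fold higher). HSP17.6C (2.59) was not called without H3.3 replicate 2 or H3.3S28A replicate 2 (0.0813 and 0.0549). COR15 and KIN genes are pairs of near-identical copies.

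Of 15 clock genes 7 rose and 7 fell, also when adjusted over the list alone, and the list as such did not shift (median 0.18, camera adjusted p = 0.824). The morning genes CCA1 (51.8 ± 1.8 to 8.91 ± 3.79 CPM, log2 fold change −2.58, adjusted p = 2.1e-06), LHY (32.8 ± 1.0 to 6.21 ± 0.87 CPM, −2.42, 2.3e-07) and PRR7 (148 ± 3.7 to 47.5 ± 4.85 CPM, −1.64, 1.3e-07, and −1.02 with the span trend removed) fell. The evening complex genes ELF4 (5.08 ± 0.08 to 74.5 ± 17.1 CPM, 3.87, 5.5e-08) and LUX (9.26 ± 0.03 to 36.1 ± 2.3 CPM, 1.97, 3.3e-07) rose. The third evening complex gene, ELF3, was at 0.18 and not called (0.192), but at 0.81 (2.0e-04) with the span trend removed. CCA1 and ELF3 are outside the rule for named genes in this pair and were added after their values were seen.

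**Figure D3:**
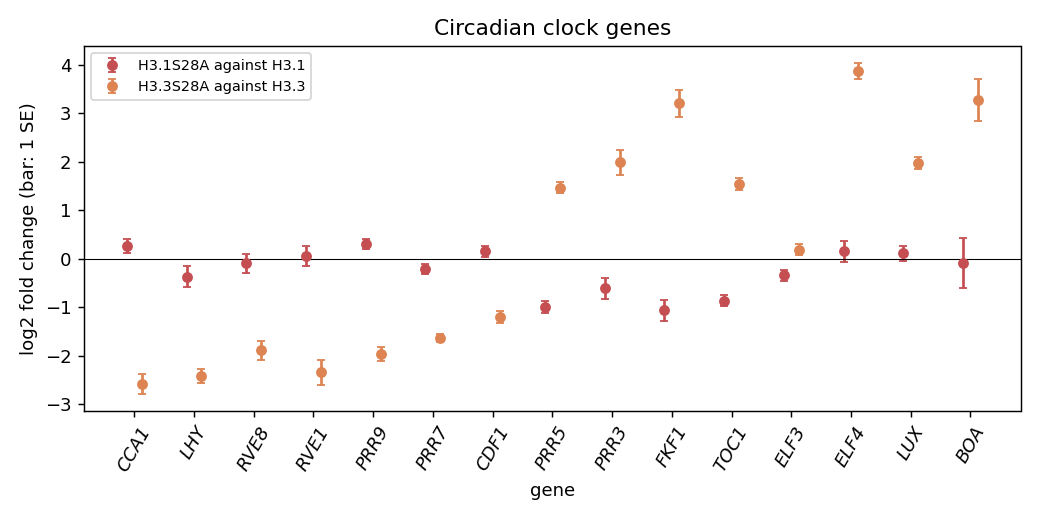
Log2 fold change of 15 clock genes with bars of 1 SE, in H3.1S28A against H3.1 and in H3.3S28A against H3.3 (2 libraries per group). In the H3.3 pair values run from −2.58 for CCA1 to 3.87 for ELF4, and in the H3.1 pair the called genes PRR5, TOC1 and FKF1 lie at −0.99, −0.87 and −1.07.

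Among the genes with large increases in H3.3S28A, some had no count in H3.3, so that their fold is only a lower limit. These included TCP1 (AT1G67260), a growth regulator of the TCP family (7.70 ± 1.24 CPM, at least 104-fold), PDF1.2c (at least 52.4-fold), the sugar transporter SWEET10 (37.8), M17 (34.9), NF-YC7 (34.5), the fruit patterning gene IND (29.1) and the loci AT5G54360 (32.0), AT4G05475 (29.1) and AT2G28085 (24.5). TCP1 had 60 and 77 counts in H3.1 and 43 and 62 in H3.1S28A, so only the H3.3 libraries lacked it. AT2G44240 had 1 count against 558 and 75 (ratio 789, 95% interval 141 to 31212.5). Among the decreases was REN1 (AT4G24580), which had 29 and 25 counts in H3.3 and none in H3.3S28A (at least 14.4-fold lower). RL1, RRTF1, BGLU22, CSLB06 and ACS11 fell as well, with 1 or 2 counts left (ratios 0.0304, 0.0372, 0.0378, 0.0509 and 0.0254, with 95% intervals that reached at most 0.194). PAKRP1, a kinesin of the phragmoplast, fell from 10.1 ± 1.5 to 0.643 ± 0.349 CPM (−3.87, adjusted p = 2.8e-06) and AHP4 from 4.69 ± 1.27 to 0.422 ± 0.301 CPM (−3.57). AT5G27230, AT5G66390, AT3G43850 and AT4G39110 had ratios of 0.0254, 0.0304, 0.0349 and 0.0550. Without H3.3S28A replicate 2, the library with the high chloroplast share, 5436 genes were higher and 5798 lower. Of the 11529 calls 10459 kept their direction, 10 were called in the other direction and the rest were not called.

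Set side by side, the lists of genes called in the 2 pairs overlapped in part. Of 18721 genes tested in both pairs, 918 were higher in both where 435.5 would be shared by independent lists, and 413 were lower in both against 308.9 (one-sided Fisher exact test across genes, p = 1.6e-158 and 5.0e-13). Genes are not independent replicates, so this test does not measure the spread between libraries. Another 237 were higher in H3.1S28A and lower in H3.3S28A, and 238 the reverse, fewer than the 482.9 and 278.6 of independent lists. Fold changes declined with gene span in both pairs, which can add to such an overlap. With the span trend removed 567 and 344 were shared, against 326.7 and 238.7. By the same one-sided Fisher exact test across genes, the overlap of lower genes was not in excess without H3.1 replicate 2 (p = 0.302) or H3.1S28A replicate 1 (0.744), or at 2-fold or more (26 genes, 0.726). The shared total of 1331 was 756 without H3.1 replicate 1 and 571 without H3.1 replicate 2. Fold changes correlated weakly across genes, which are not independent replicates (Pearson r = 0.18, Spearman rho = 0.24, and 0.11 and 0.15 with the span trend removed), and r was 0.02 without H3.1S28A replicate 1.

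The test of the difference itself, the effect in H3.1S28A minus that in H3.3S28A, called 7829 of 20052 genes (39.0%), 4896 with the higher effect in H3.1S28A and 2933 with the lower. The higher share was 62.5%, and with the span trend removed it was 49.6% (3334 and 3388 genes). Of the genes called in opposite directions in the 2 pairs, 237 and 237 were also called here. Clock genes differed most completely, 7 of 15 with the higher effect in H3.1S28A and 8 with the lower, and the list went both ways (camera adjusted p = 0.234). The DNA methylation (10 higher of 13, camera adjusted p = 4.4e-04), Polycomb (12 higher and 1 lower of 29, 0.0022) and cell cycle lists (14 higher and 2 lower of 26, 0.0044) were higher, and the first 2 were at 0.205 and 0.0808 with the span trend removed. Cold (7 lower of 12, 1.1e-04), defence (7 lower and 2 higher of 19, 0.0016), floral (6 lower of 10, 0.0018), meristem (4 lower of 11, 0.0182), flowering time (11 lower and 3 higher of 29, 0.0338) and jasmonate lists (3 lower of 16, 0.0338) were lower. With an estimated correlation these 9 lists had adjusted p = 0.540 to 0.640. Fry, which tests a list against no change, called 7 of them, not the flowering time (0.0622) and jasmonate lists (0.295), and 5 others. The jasmonate list was not called without H3.1 replicate 2, H3.1S28A replicate 2, H3.3 replicate 1 or H3.3S28A replicate 2 (0.544, 0.0920, 0.0826 and 0.159) with the trend removed (0.0843) or without the count filter (0.0534), and the flowering time list not without H3.3S28A replicate 1 (0.121).

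The other lists did not differ by camera. Leaf photosynthesis genes, 11 of 22 higher, were at adjusted p = 0.0781, but at 5.3e-05 with the span trend removed (adjusted p = 0.470 with an estimated correlation), at 0.0079 without the count filter and at 0.0196 and 0.0276 without H3.1 replicate 2 or H3.3S28A replicate 1. The histone lists, H3.1 genes (2 of 5 higher, 0.669) and other H3 genes (1 higher and 2 lower of 7, 0.387), were not called. Neither were the seed (1 of 4 lower, 0.387), DNA damage (2 of 4 higher, 0.619), anther (1 of 5 higher, 0.619), pollen (1 of 5 higher, 0.556), root (1 of 6 higher, 0.619) and heat shock genes (1 higher and 2 lower of 12, 0.445). Adjusted over the list alone, the counts of higher and lower members changed in 6 lists: Polycomb 14 and 1, cell cycle 15 and 2, floral 0 and 7, defence 3 and 7, cold 1 and 7, and leaf 12 and 0, and in 3 further lists by 1 gene.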

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

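The tests against anther or pollen content, the gene span trend, developmental stage, RNA integrity and clock phase were chosen after the results were seen, while the tests of the difference between the pairs were chosen before the data were examined. What brought the results below here was a test of that difference, the effect in H3.1S28A minus the effect in H3.3S28A. It called 7829 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It also called 9 lists by camera: flowering time regulators (adjusted p = 0.0338), floral organ identity genes (0.0018), meristem regulators (0.0182), Polycomb and H3K27 genes (0.0022), DNA methylation and silencing genes (4.4e-04), cell cycle genes (0.0044), salicylic acid and defence genes (0.0016), jasmonate genes (0.0338) and cold genes (1.1e-04). None of the 9 passed with an estimated correlation, where no list had an unadjusted p under 0.05. With it camera did not call even the floral list of the H3.3 pair, where all 10 genes tested were higher (adjusted p = 0.354). A list not called in that way is therefore not shown to be unchanged. Fry, which tests a list against no change, called 7 of the 9, not the flowering time (0.0622) and jasmonate lists (0.295).

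The first pattern is the rise of the floral organ identity list in H3.3S28A. Anthers or pollen mixed into the H3.3S28A samples are argued against by the 35 anther, tapetum and pollen markers, whose summed level went from 31.4 ± 2.81 to 16.6 ± 2.91 CPM (SD, n = 2), a ratio of 0.529. The gene span trend is argued against because the list stayed called once the trend was removed (camera adjusted p = 3.9e-26, with 4.5e-18 before and 0.354 with an estimated correlation, the highest value among the alternatives). AP1, CAL and LFY of the flowering time list, picked after their values were seen, were higher in H3.3S28A. AP1 was at 0.0507 and 0 CPM in H3.3 against 3.99 and 3.04, and CAL at 0 and 0.0519 against 0.972 and 0.389. LFY had 2 and 5 counts against 20 and 6, too few to be tested. Such rises go with a later stage and with a direct effect alike. Young flowers or a later stage of the H3.3S28A plants cannot be told apart from a direct effect of the mutation on these genes, since stage was confounded with genotype (flowering time list at adjusted p = 0.0547, 4.1e-04 with the trend removed, 0.705 with an estimated correlation, 0.575 with both and 0.0966 by fry). De-repression of Polycomb targets in H3.3S28A is a hypothesis these RNA counts could not separate from that, as it would take H3K27me3 at these genes in plants of matched stage to decide it, and no chromatin data were analysed here.

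The second pattern is the lower level of the Polycomb, DNA methylation and cell cycle lists in H3.3S28A. Random lists matched on gene span and expression had medians down to the observed ones for Polycomb genes (percentile 24.8 of 10000 random lists) and DNA methylation genes (percentile 4.94), so that the span trend may account for these 2 lists. With the trend removed their calls ended (medians from −0.62 to −0.34 and from −1.31 to −0.38, SD across members from 0.90 to 0.68 and from 0.71 to 0.73, camera adjusted p = 0.150 and 0.127) because the medians moved toward 0. For the cell cycle list the trend is argued against as the whole cause, since 0 of the 10000 random lists matched on gene span had a median as low and the list stayed called with the trend removed (median from −0.82 to −0.66, camera adjusted p = 6.0e-05), though not with an estimated correlation (adjusted p = 0.612 before and 0.575 after the removal). RNA integrity or library preparation that differed between the H3.3 and H3.3S28A groups stays open as the source of the trend: the 4 pairs of an H3.3S28A with an H3.3 library had absolute rank correlations with span of 0.492 or more, against at most 0.189 within any group, but these differences were confounded with genotype.

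The third pattern is the opposite movement of morning and evening clock genes in H3.3S28A. Outside the clock list, 5 evening genes and 9 dawn genes chosen from memory differed by 2.70 in median log2 fold change, and by 2.48 with the span trend removed (SD across genes 0.84 for evening and 1.21 for dawn genes, whose median was −1.41). An exact permutation test over all 2002 splits of the 14 genes, which are not independent replicates, gave p = 0.0075, and in the H3.1 pair, where the difference was 0.04, p = 0.775. A different clock phase at harvest may therefore account for this pattern in the H3.3 pair, and harvest time and a changed clock predict the same values and were not separated. Exceptions in the H3.3 pair were RVE4, which did not change by the test (−0.13, adjusted p = 0.260), RVE2, which rose (1.09), and the evening gene GI of the flowering list (−0.20, adjusted p = 0.224), and the value of JMJD5, which is JMJ30 of the Polycomb list, had been seen before it was used.

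Single genes whose effect differed are given with CPM in H3.1, H3.1S28A, H3.3 and H3.3S28A from a joint scaling of the 2 tables. A difference between plant lines at a single gene was not separated from an effect of the mutation. ABCG19 was at 39.8, 0.0704, 21.2 and 25.8 CPM (adjusted p = 3.8e-08). TCP1 was at 3.08, 2.83, 0 and 7.63 CPM (2.6e-06). REN1 was at 1.55, 1.02, 1.38 and 0 CPM (9.4e-04). PR1 was at 4.62, 0.219, 5.22 and 232 CPM (0.0012, but 0.579 without H3.1 replicate 1). AT1G71000 was at 0.677, 0.0988, 0 and 1.38 CPM (2.2e-04). AT5G45469 was at 0.812, 1.04, 0.768 and 0 CPM (0.0020). AT1G33760 was at 0, 0.318, 1.18 and 0.129 CPM (0.0065).

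ACS11 was at 0.158, 0.380, 1.25 and 0.0394 CPM (adjusted p = 0.0067, but 0.0596 without H3.1S28A replicate 1). AT5G04238 was at 0.653, 1.96, 0.204 and 0 CPM (0.0139, but 0.0552 without H3.3 replicate 1 and 0.0602 without H3.3S28A replicate 1). M17 was at 0.0445, 0, 0 and 2.85 CPM (0.0173, but 1.00 without H3.1 replicate 2). AT3G44006 was at 0, 0.0988, 1.02 and 0.183 CPM (0.0264, but 0.0563 with a replicate block), and was called only without H3.1S28A replicate 1 or H3.3S28A replicate 2 among the fits that left out 1 library. Its adjusted p was 0.0715 and 0.0710 without H3.1 replicate 1 and 2, 0.158 without H3.1S28A replicate 2, 0.0636 and 0.0539 without H3.3 replicate 1 and 2, and 0.0587 without H3.3S28A replicate 1. AT1G44542 was at 0.0455, 0, 0 and 1.07 CPM (0.0355, but 0.0569 with a replicate block), but at 1.00 without H3.1 replicate 1, 0.0684 without H3.1S28A replicate 2, 0.0610 and 0.0631 without H3.3 replicate 1 and 2, and 0.0684 without H3.3S28A replicate 2.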

How the results depend on the processing

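Removal of the gene span trend, alone or with an estimated correlation, was chosen after seeing the data, and every other alternative was chosen before the data were examined. At a fold change of at least 2 the counts were 448 genes in the H3.1 pair, 4499 in the H3.3 pair, 3843 for the difference and 103 in both pairs, as that limit removes genes by construction. Leaving out 1 library gave 1152 (without H3.1 replicate 2) to 3480 genes (without H3.1S28A replicate 2) in the H3.1 pair, 8875 to 11234 in the H3.3 pair, 6209 to 7642 for the difference, 571 to 1962 in both pairs (without the same 2 libraries) and a correlation of fold changes of 0.02 (0.0214, without H3.1S28A replicate 1) to 0.26 (0.256). The lone library left in a group was taken to vary like the other groups. Without the count filter that correlation was 0.10 (0.0995). DESeq2 called 1850, 9797, 6678 and 968. The cause was not tested.

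Lists called by camera numbered 7, 6 and 9 in the H3.1 pair, the H3.3 pair and the difference. With an estimated correlation they were 0, 0 and 0 (0, 1 and 0 lists at an unadjusted p under 0.05). By fry they were 0, 11 and 12 (0, 11 and 14 unadjusted), and with the span trend removed 3 in the H3.1 pair, or 0, 0 and 0 with an estimated correlation as well (0, 1 and 0 unadjusted). The jasmonate list of the H3.1 pair ran from 6.1e-17 (without H3.1 replicate 1) to 0.496 (without H3.1S28A replicate 2), and reversed without H3.1 replicate 2 (0.376). With the span trend removed, HTR2 (−0.54), HTR13 (−0.58), HTR4 (−0.29), HTR8 (−0.0661) and PHO1 (0.0303) reversed in the H3.3 pair, because they are short, or for PHO1 long, genes. The cause of the others was not tested. Named genes kept or still lacked a call in 747 comparisons with an alternative (H3.1 pair), 1119 (H3.3 pair) and 158 (the difference). They lost the call in 77, 30 and 18, and gained a call in the same direction in 9 (H3.1 pair) and 3 (H3.3 pair). Direction was compared only where a gene was called in either fit. Uncalled genes could therefore change sign, as HTR2 did in the H3.1 pair (0.04, and −0.23 with the span trend removed). No scaling moved the median of all genes by over 0.1, but the scalings used assume that most genes are unchanged. That assumption was not tested, and 58.4% of genes were called in the H3.3 pair.

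Libraries share replicate numbers, and the labels do not say that equal numbers were handled together. Differences between libraries of equal number correlated at −0.00 in the H3.1 pair and 0.02 in the H3.3 pair (2 pairs each). No pairing by number was seen, but so few libraries could not exclude shared handling. A replicate block gave 2836, 11472 and 7527 genes, 1497 in both pairs, a correlation of 0.19 and 7, 6 and 9 lists, ended the difference calls of AT3G44006 (0.0563) and AT1G44542 (0.0569) and called PI (0.0386) and SOC1 (0.0136) in the H3.1 pair. With library totals of 12865999 to 24449528, a count of 0 leaves levels under 0.123 to 0.233 CPM open.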

Other observations

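The gene families below were chosen after the data were seen. In H3.3S28A, all 5 lipid transfer protein genes tested were higher (camera adjusted p = 3.6e-06, and 0.0038 with the gene span trend removed), with LTP5 going from 144.7 to 584 CPM, LTP3 from 3.90 to 55.6 CPM and LTP4 from 1.84 to 49.5 CPM. Of 9 SWEET sugar transporter genes 6 were higher and none lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (1.3e-04, and 7.1e-05 with the trend removed), among them SWEET17 (log2 fold change 2.14), SWEET1 (1.45), SWEET12 (1.12) and SWEET11 (0.82). Plant defensin genes were higher in 6 and lower in 2 of 12 cases (5.9e-04 and 0.0051). Arabinogalactan proteins (16 higher, 1 lower of 25), xyloglucan endotransglucosylases (13 and 1 of 22), expansins (10 and 1 of 17) and SAUR genes (12 and 0 of 15) were called up as families (5.9e-04, 0.0021, 0.0057 and 0.0089), and these 4 calls ended with the trend removed (0.739, 0.0518, 0.0874 and 0.437). With an estimated correlation no family of this pair passed, the lowest adjusted p being 0.310, or 0.495 with the trend removed. Near-identical copies, as among lipid transfer protein and defensin genes, are uncertain because the treatment of reads that map to several places is not stated.

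In H3.1S28A, flavonoid pathway genes were lower in 7 and higher in 1 of 15 cases (camera adjusted p = 0.0038, and 0.0054 with the trend removed). In H3.3S28A they were higher in 6 and lower in 6 of 16 cases (0.125, and 0.0078 in the downward direction with the trend removed). In H3.1S28A DFR, of anthocyanin synthesis, was at a log2 fold change of −1.72 and TT4, chalcone synthase, at −0.89. Xyloglucan endotransglucosylases, which remodel the cell wall, were higher in 9 and lower in 2 of 19 cases (0.0031 and 0.0099), while expansins were lower in 5 and higher in 3 of 15 (0.0269 and 0.0104). UMAMIT transporters were lower in 6 of 30 cases and higher in none by edgeR (0.0491, and 0.101 with the trend removed). WRKY factors were lower in 2 of 42 cases and higher in none by edgeR (0.0269 and 0.0288). Arabinogalactan proteins (7 higher, 2 lower of 24) and SAUR genes (3 and 1 of 14) were called up, both at 0.0038, and these 2 calls ended with the trend removed (0.397 and 0.184). With an estimated correlation the adjusted p of all families of this pair were 0.618 or higher, and 0.577 or higher with the trend removed.

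Neighbours of 3 genes at or near 0 counts in one group, also chosen after the values were seen, had these changes in the same pair. Beside ABCG19 in the H3.1 pair, ABCG18 was at −0.03 (adjusted p = 0.920), TT5 at −0.11 (0.711) and AT3G55140 at 0.36 (0.0588). Beside TCP1 in the H3.3 pair, AT1G67250 was at 0.39 (0.0336), RTFL21 at −1.04 (0.0425) and LINC1 at −2.09 (1.3e-07). Beside REN1 in the H3.3 pair, AT4G24590 was at 0.12 (0.551), DIC2 at −2.11 (9.4e-04) and UBP16 at −1.08 (4.0e-05). Of all genes tested 58.4% were called in the H3.3 pair and 13.5% in the H3.1 pair, so called neighbours do not set these places apart. LFY, the meristem identity gene of flowers, had 4, 11, 5 and 1 counts in the H3.1 and H3.1S28A libraries and 2, 5, 20 and 6 in the H3.3 and H3.3S28A libraries, too few to be tested.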
